A study of Mus musculus with 75 samples.

How the data were processed

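Per the labels, total RNA was extracted from kidney with Trizol, labelled with Cy5 and hybridised with Cy3-labelled Mouse Universal Reference RNA, a mixture of cell lines, to Agilent 44K arrays, without dye swaps. Per the file headers, Agilent Feature Extraction 10.7.3.1 made the values of 27 arrays (day 0 and normal controls) and 11.5.1.1 those of the other 48, with probe annotation on the mouse builds mm8 and mm9. The deposited files give each spot's median feature signal and median local background as an intensity without normalization. They also give a log10 ratio of red to green, which per the file headers Feature Extraction made after background subtraction, spatial detrending and dye normalization. The authors' series matrix holds the same log10 ratios: all values of its 44996 probes equalled the scanner files' ratios within 0.6 percent, with array medians between -0.0626 and 0.00718. It was used as an alternative source only. No column belonged to another series (0 of them).

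The comparisons, gene lists, thresholds and alternatives were chosen before the data were examined, except where stated. Values were built from the median signals, because a mean signal was not in every file. Background was corrected by normexp with an offset of 50, and log2 ratios of red to green were normalised within each array by loess in limma 3.58.1 (R 4.3.3, with data.table, version 1.17.8). A spot whose local background was marked as an outlier took the array's median local background. That choice was made after the spread of each array had been seen and before any comparison, and the spot's own background is among the alternatives. Of 45018 features, 1639 control spots and the spots marked as outliers were left out, and replicate spots were averaged to 41174 probes. Probes well above background in the kidney channel on at least 4 arrays were kept (35808). Symbols came from the systematic accession for 23374 probes through the reference table, and 8128 probes kept the file's own name. The probe with the highest mean intensity stood for each gene (7873 genes had several), which left 18717 genes. Missing values filled 530 of 1403775 cells.

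A model with a mean for each of the 13 groups was fitted to the 75 arrays by limma with moderated variances, 2-sided, and p was adjusted by Benjamini and Hochberg over all genes of a comparison. A gene passed at adjusted p under 0.05. The gene lists, 33 in number, were sets of known kidney, immune and stress markers tested by camera with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A change given as at least a fold is a lower bound, for a gene not above background on any array of 1 group. Genes were named by rule: a fixed panel of 17 genes in every comparison of obstructed with sham, the 6 highest and 6 lowest called genes with all obstructed arrays on 1 side of the sham mean (5 and 5 in the other comparisons), and the largest members of each list. A few genes are not reported here. SE is limma's, from the pooled variance. Batches were read from the file headers as slide and scan day.

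The method was tested on simulated arrays of the 18717 genes, drawn with each gene's own spread and no batch, with changes of 1.5, 2 and 4-fold added to a few genes. For the 1-day clamp at day 0 the model called 61.2%, 88.1% and 98.5% of them, at day 10 68.7%, 92.5% and 100%, and at day 28 70.2%, 88.1% and 100%. For the 5-day clamp it called 65.7%, 92.5% and 98.5% at day 0, 76.1%, 82.1% and 100% at day 10, and 59.7%, 89.6% and 100% at day 28. Of 40 lists of 25 genes drawn without correlation camera called the 1 shifted (5-day clamp, day 10) and 0 others. This cannot test its preset correlation.

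Alternatives that were set before the data were seen covered array weights, the scanner software's log ratio, the series matrix, Aquantile between arrays, median centring in place of loess, no or a stricter filter on dim probes, the mean of a gene's probes, only the compared groups in the model, slide as a random block or fixed term, scan day as a fixed term, the replicate number as a block, and leaving out each array. Others, named below, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.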

Results

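Gene expression was measured in the kidneys of C57BL/6 mice whose left ureter was clamped for 1 or 5 days, a model of ureteral obstruction reversed by taking the clamp off. Kidneys were collected 0, 10 and 28 days after clamp removal. Sham mice had the ureter dissected but not tied, and normal control kidneys were measured as well. Each of the 75 arrays compared kidney RNA (red dye) with a reference RNA pooled from cell lines (green dye), and a value is the log2 ratio of kidney to reference. After the 1-day clamp there were 6, 5 and 6 obstructed arrays at days 0, 10 and 28, and after the 5-day clamp 6, 8 and 5. The sham groups held 6, 6 and 6 arrays for the 1-day clamp and 5, 6 and 6 for the 5-day clamp, and there were 4 normal controls. The labels call the replicates biological.

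On 69 arrays between 61.1% and 92.7% of the probes stood well above background in the kidney channel. The other 6 arrays had 17.2% to 36.2%. These weak arrays were obstructed replicates 1 to 4 and sham replicates 5 and 6 of the 1-day clamp at day 0, all scanned on the same day. For the 1-day clamp at day 0 the main values, but not every list member, are also given without these 6 arrays. The arrays came from 23 slides and 10 scan days. Obstructed arrays of the 5-day clamp at day 28 shared no slide or scan day with their shams. Those of the 1-day clamp at day 0 shared scan days with their shams but no slide. The differences by duration and recovery that use this comparison carry the same limit. The normal controls had their own slides and scan days.

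**Figure D1:**
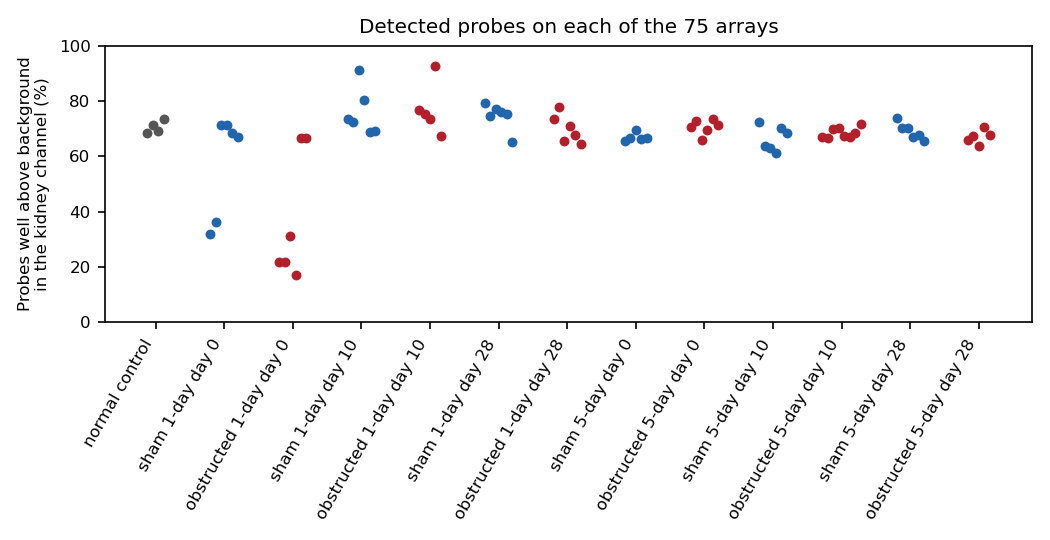
Percent of probes well above background in the kidney channel, 1 point per array, by group. The 6 weak arrays (1-day, day 0) had 17.2% to 36.2%.

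A first comparison asked what 1 day of obstruction had done to the kidney at the moment of release (6 obstructed and 6 sham arrays; log2 change ± SE from limma, adjusted p under 0.05 to pass). The fibrinogen chain gene Fgg (6.76 ± 0.38) rose most, and the blood-clotting and acute-phase genes Fgb (4.97 ± 0.41) and Saa2 (3.41 ± 0.26) rose too. Damaged tubule cells are known to make osteopontin (Spp1, 5.17 ± 0.42), keratin 20 (Krt20, 3.75 ± 0.52), the iron-carrier trap lipocalin 2 (Lcn2, 2.70 ± 0.35) and kidney injury molecule 1 (Havcr1, 1.92 ± 0.73), and all 4 rose. So did the metal-binding protein gene Mt2 (3.46 ± 0.28), complement C3 (3.15 ± 0.53) and the protease inhibitor Timp1 (2.98 ± 0.27). Genes of the distal nephron fell: the salt carrier Slc12a1 (-5.07 ± 0.43), the growth factor Egf (-4.83 ± 0.25), the lactate carrier Slc16a7 (-4.13 ± 0.43) and the water channel Aqp2 (-2.84 ± 0.21). Wfdc15b (-4.61 ± 0.40), the peptide hormone gene Cck (-4.29 ± 0.45) and the lipid-droplet gene Cidea (-4.42 ± 1.23) fell as well.

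Without the 6 weak arrays (2 obstructed and 4 sham), these directions stayed: Fgg was 5.58, Fgb 4.10, Saa2 4.79, Spp1 3.83, Krt20 4.81, Lcn2 4.04, Havcr1 3.43, Mt2 3.14, C3 3.14 and Timp1 3.28. The decreases were smaller: Slc12a1 -2.81, Egf -3.25, Slc16a7 -3.32, Aqp2 -1.27, Wfdc15b -1.66 and Cck -2.68, while Cidea no longer passed (-3.69, adjusted p = 0.172). Passing only with the weak arrays in were the adhesion molecule Vcam1 (1.03 ± 0.34 with all arrays, 0.57 without the weak ones), fibronectin (Fn1, 0.75 ± 0.19 and 0.16), the macrophage marker Cd68 (1.0 ± 0.24 and 0.48), the phosphate carrier Slc34a1 (-1.13 ± 0.25 and -0.27) and klotho (Kl, -2.58 ± 0.34 and -0.33). Vcam1, Fn1 and Cd68 turned lower with every array centred on its median (-0.221, -0.857 and -0.224), and Slc34a1 and Kl turned higher with the scanner software's own log ratio (1.52 and 0.26). The collagens Col1a1 (0.55 ± 0.31) and Col3a1 (0.40 ± 0.31), smooth muscle actin (Acta2, -0.14 ± 0.19), uromodulin (Umod, 0.58 ± 0.34) and the organic anion carrier Slc22a6 (-0.081 ± 0.38) did not pass.

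In all, 3286 genes rose and 3930 fell, of 18717 tested, 440 and 1102 of them at least 2-fold. Leaving the weak arrays out, 1501 rose and 2225 fell, and 2891 of the 7216 genes were called the same way and 7 the opposite way. With slide as a random block 1163 rose and 1811 fell. Centring each array on its median gave 2842 and 9336 and shifted the median of all genes by -0.484. The scanner software's log ratio gave 2491 and 4511. Within the scan day of the weak arrays (4 obstructed, 2 sham) 1321 rose and 1648 fell.

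Among the 33 gene lists, 10 were higher and 11 lower than other genes by camera at its preset correlation, and none of these 21 held with an estimated correlation. Member counts are over all genes, and one adjusted over the list alone follows where it differed (in-list). The adjusted p of a list is camera's. Among tubular injury genes 17 of 22 rose, 3 fell (18 and 3 in-list) and 2 did not pass, with Gdf15 (2.43 ± 0.20), a stress cytokine, beside Spp1, Krt20 and Lcn2. Their median was 1.32 (adjusted p = 8.07e-10, adjusted p = 0.0505 with an estimated correlation). Without the weak arrays their median was 1.23 and the adjusted p 2.18e-11. The immediate-early genes, switched on within minutes by stress, moved the same way: 15 of 20 rose (16 in-list) and 5 did not pass, led by Ccn1 (2.06 ± 0.20), Myc (1.93 ± 0.18) and Egr2 (1.90 ± 0.34). Their median was 1.34 (adjusted p = 7.78e-14, adjusted p = 0.0505 with an estimated correlation), and 1.35 without the weak arrays. Among cell cycle genes 32 of 33 rose (32 rose and 1 fell in-list) and 1 did not pass, and 13 rose without the weak arrays. With all arrays the mitotic genes were led by Bub1 (1.73 ± 0.41), Ccnb1 (1.72 ± 0.38) and Top2a (1.57 ± 0.36). Their median was 1.05 (adjusted p = 1.92e-15, adjusted p = 0.155 with an estimated correlation), and 0.55 (adjusted p = 3.34e-09) without the weak arrays. Of the chemokine and cytokine genes 17 of 31 rose, 5 fell (18 and 5 in-list) and 9 did not pass. The neutrophil attractant Cxcl1 (2.97 ± 0.36) rose, Cxcl5 was at least 2.8-fold higher, and Cxcl12 (-2.22 ± 0.31) and Ccl19 (-1.69 ± 0.29) fell. The list's median was 0.47 (adjusted p = 0.000239, adjusted p = 0.193 with an estimated correlation), and 0.37 without the weak arrays.

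Macrophage and monocyte markers shifted less: 12 of 24 rose, 1 fell (13 and 2 in-list) and 11 did not pass, with Cd14 (2.21 ± 0.23) and Trem2 (1.51 ± 0.35). Their median was 0.53 (adjusted p = 0.000552, adjusted p = 0.351 with an estimated correlation). It was 0.27 (adjusted p = 0.00863) without the weak arrays. Among B and plasma cell genes 6 of 17 rose, 1 fell and 10 did not pass (Ms4a1 1.57 ± 0.35, Pou2af1 1.15 ± 0.27; median 0.22, adjusted p = 0.0244, adjusted p = 0.268 with an estimated correlation). They lost the call without the weak arrays (adjusted p = 0.373). Extracellular matrix genes also lost it: 10 of 30 rose, 2 fell (10 and 3 in-list) and 18 did not pass, with Lox (1.26 ± 0.34). Their median was 0.39 (adjusted p = 0.00121, adjusted p = 0.511 with an estimated correlation), and -0.18 (adjusted p = 0.817) without the weak arrays. Cell stress lists were called higher with smaller shifts. For p53 and senescence 10 of 19 rose, 2 fell and 7 did not pass (median 0.32, adjusted p = 0.00537, adjusted p = 0.173 with an estimated correlation; Cdkn1a 1.31 ± 0.28). For hypoxia 6 of 18 rose, 3 fell and 9 did not pass (median 0.33, adjusted p = 0.0244, adjusted p = 0.351 with an estimated correlation; Hmox1 1.73 ± 0.19). For NRF2 and antioxidant genes 10 of 19 rose, 3 fell and 6 did not pass (median 0.50, adjusted p = 0.00539, adjusted p = 0.0674 with an estimated correlation; Gpx3 1.56 ± 0.39). With the weak arrays left out only the NRF2 list stayed called among these 3 (adjusted p = 0.0327, against 0.0885 and 0.855), and median centring turned all 3 and the matrix list lower.

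Every nephron segment list was lower. Of the collecting duct principal cell genes 17 of 18 fell and 1 did not pass, with the water channels Aqp3 (-3.25 ± 0.26) and Aqp4 (-2.76 ± 0.57) and the vasopressin receptor Avpr2 (-2.76 ± 0.32). Their median was -2.22 (adjusted p = 1.55e-11, adjusted p = 0.0778 with an estimated correlation). It was -1.13 without the weak arrays. Among genes of acid-secreting intercalated cells 17 of 17 fell, with the anion exchanger Slc4a1 (-3.52 ± 0.32) and the ammonia channel Rhbg (-3.33 ± 0.36). Their median was -1.64 (adjusted p = 2.87e-11, adjusted p = 0.121 with an estimated correlation), and -0.89 without the weak arrays. In the thick ascending limb 13 of 17 fell (14 in-list) and 4 did not pass, with Sostdc1 (-3.96 ± 0.47) and the potassium channel Kcnj1 (-3.27 ± 0.37). Their median was -1.33 (adjusted p = 1.23e-08, adjusted p = 0.0674 with an estimated correlation). Leaving the weak arrays out gave -0.53 (adjusted p = 3.65e-05). In the distal convoluted and connecting tubule 12 of 16 fell (1 rose and 12 fell in-list) and 4 did not pass, with calbindin (Calb1, -4.02 ± 0.35) and the calcium exchanger Slc8a1 (-3.20 ± 0.43), and Pvalb at least 5.56-fold lower. Their median was -1.86 (adjusted p = 2.24e-09, adjusted p = 0.0674 with an estimated correlation), and -0.90 without the weak arrays. Proximal tubule genes followed: 1 of 31 rose, 24 fell (1 and 25 in-list) and 6 did not pass, with G6pc (-3.27 ± 0.34) and Slc6a19 (-2.88 ± 0.53). Their median was -1.18 (adjusted p = 6.68e-09, adjusted p = 0.144 with an estimated correlation). Without the weak arrays the proximal median was -0.15 (adjusted p = 0.0353), and with the scanner software's log ratio the list was higher, not lower (adjusted p = 0.559).

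Endothelial genes fell nearly throughout. Of these 19 of 20 fell (20 in-list) and 1 did not pass, with the capillary genes Emcn (-3.15 ± 0.36), Ptprb (-3.09 ± 0.49) and Plvap (-2.73 ± 0.24). Their median was -1.58 (adjusted p = 1.85e-12, adjusted p = 0.144 with an estimated correlation). It was -1.06 (adjusted p = 1.57e-09) without the weak arrays. Among podocyte genes 12 of 18 fell (15 in-list) and 6 did not pass, with Tcf21 (-2.04 ± 0.42). Their median was -0.72 (adjusted p = 8.67e-06, adjusted p = 0.193 with an estimated correlation), and -0.54 without the weak arrays. For the citric acid cycle and respiratory chain 25 of 32 fell (27 in-list) and 7 did not pass, with Suclg1 (-1.24 ± 0.24) and Sdhb (-1.18 ± 0.23). Their median was -0.58 (adjusted p = 7.51e-11, adjusted p = 0.144 with an estimated correlation), and -0.67 without the weak arrays. Among fatty acid oxidation genes 12 of 30 fell and 18 did not pass (Acot12 -1.79 ± 0.57; median -0.35, adjusted p = 0.00537, adjusted p = 0.497 with an estimated correlation). This list was not called without the weak arrays (adjusted p = 0.451) or with the scanner software's log ratio, which turned it higher (adjusted p = 0.601). Among renin-angiotensin genes 1 of 10 rose, 8 fell and 1 did not pass (Agtr1a -2.15 ± 0.40; median -0.95, adjusted p = 0.0146, adjusted p = 0.355 with an estimated correlation). Leaving the weak arrays out gave adjusted p = 0.938. Among perirenal fat genes 6 of 13 fell (9 in-list) and 7 did not pass, with Ucp1 (-3.96 ± 1.24) and Adipoq (-2.90 ± 0.93). Their median was -2.11 (adjusted p = 0.013, adjusted p = 0.536 with an estimated correlation), and -1.81 (adjusted p = 0.0438) without the weak arrays.

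Not called were fibroblast (1 rose and 6 fell of 18), T and NK cell (5 rose and 3 fell of 21), neutrophil (2 of 14 rose), complement (3 rose and 6 fell of 19), MHC class II (1 rose and 4 fell of 11), MHC class I (1 rose and 1 fell of 10) and interferon genes (5 rose and 4 fell of 26). Neither were smooth muscle (6 of 12 fell), urothelium (1 rose and 6 fell of 15), red blood cell (3 of 6 fell), sex-linked (0 of 5 passed) and adrenal genes (1 of 12 fell, median 0.032, mean -0.14). Without the weak arrays the fibroblast list (median -0.71, adjusted p = 0.00362) and smooth muscle (adjusted p = 0.0166) were called lower. With an estimated correlation neither was (adjusted p = 0.451 and 0.313). Falling without the weak arrays were 11 principal cell, 13 intercalated cell, 8 thick ascending limb, 9 distal convoluted tubule, 7 proximal tubule and 15 endothelial genes. On the weak scan day the injury, principal cell and endothelial medians were 1.01, -1.20 and -0.94, but obstructed arrays were weaker there. Weak signal thus stays open.

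Release after 1 day was followed to day 10 (5 obstructed, 6 sham) and day 28 (6 and 6) to ask how far the kidney returned to the sham state. At day 10 only 5 genes rose and 0 fell: the collagen gene Col3a1 (1.55 ± 0.33), the elastic fibre genes Mfap4 (1.47 ± 0.30) and Mfap2 (1.06 ± 0.21), and the interferon-induced Parp14 (0.98 ± 0.19) and Rnf213 (0.66 ± 0.13). All 5 obstructed arrays lay above the sham mean for each. At day 28 a single gene passed, the transcription factor gene Htatsf1 (0.67 ± 0.13). By limma 2014 genes at day 10 and 1581 at day 28 had an unadjusted p under 0.05. The scanner software's log ratio called 0 genes at day 10, and without the weak arrays 63 rose and 6 fell there. With slide as a random block 65 rose and 16 fell at day 10, and 0 at day 28. Array weights called 210 genes at day 10 and 2806 at day 28, and leaving out 1 array gave 0 to 8 and 0 to 5.

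The injury and transport genes that had moved at release did not pass at either time. At day 10 and day 28 Havcr1 was -0.75 ± 0.77 and -0.51 ± 0.73, Lcn2 0.49 ± 0.37 and 0.91 ± 0.35, Spp1 1.13 ± 0.44 and 0.74 ± 0.42, Timp1 0.70 ± 0.28 and 0.33 ± 0.27, and C3 0.89 ± 0.55 and 1.02 ± 0.53. Vcam1 was 1.34 ± 0.35 and 1.23 ± 0.34, Cd68 0.26 ± 0.25 and 0.35 ± 0.24, Col1a1 1.46 ± 0.32 and 0.93 ± 0.31, Fn1 0.12 ± 0.20 and 0.15 ± 0.19, and Acta2 0.099 ± 0.20 and 0.15 ± 0.19; Col3a1 was 0.87 ± 0.31 at day 28. Without obstructed replicate 10, Lcn2, Spp1, Timp1 and C3 at day 10 were 0.030, 0.74, 0.41 and 0.43, and C3 was 1.37 without replicate 8. Sham replicate 17 was low in Slc22a6 at day 28. For tubule genes the values were Egf 0.02 ± 0.27 and -0.24 ± 0.25, Aqp2 0.011 ± 0.22 and 0.044 ± 0.21, Slc34a1 -0.14 ± 0.26 and -0.27 ± 0.25, Slc22a6 -0.10 ± 0.39 and 0.52 ± 0.38, Umod 0.045 ± 0.36 and -0.30 ± 0.34, and Kl 0.18 ± 0.36 and -0.27 ± 0.34.

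As groups, 13 lists were higher and 2 lower at day 10, and 11 higher and 1 lower at day 28, none of them with an estimated correlation. Members passed over all genes only in the matrix list (Col3a1) and the fibroblast list (Mfap4) at day 10. Interferon response genes led at day 10, with Gbp3 (0.99 ± 0.61) and Ifit1 (0.93 ± 0.23) as the largest values. Their medians at days 10 and 28 were 0.60 and 0.17 (adjusted p = 4.25e-21 and 5.33e-05, adjusted p = 0.0561 and 0.483 with an estimated correlation). Within the 2 scan days that held both groups at day 28 (2 against 2, and 4 obstructed against 1 sham) the interferon median was 0.29 and -0.33. Extracellular matrix genes had medians of 0.48 and 0.33 (adjusted p = 3.55e-16 and 1.55e-11, adjusted p = 0.201 and 0.203 with an estimated correlation). Fibroblast genes had 0.35 and 0.24 (adjusted p = 2.54e-06 and 4.37e-05, adjusted p = 0.218 and 0.217 with an estimated correlation), and injury genes 0.33 and 0.38 (adjusted p = 0.000277 and 6.5e-09, adjusted p = 0.229 and 0.141 with an estimated correlation). Macrophage and monocyte genes had 0.46 and 0.43 (adjusted p = 3.21e-07 and 2.03e-10, adjusted p = 0.229 and 0.175 with an estimated correlation), with Lyz2 (1.13 ± 0.40 and 1.45 ± 0.38) and Ms4a7 (1.44 ± 0.35 and 1.09 ± 0.34) not passing. Adjusted over the list alone, 20 interferon, 15 matrix and 9 macrophage genes rose at day 10, and 0, 6 and 7 at day 28.

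Antigen presentation was shifted in the same direction: MHC class II had medians of 0.56 and 0.32 (adjusted p = 2.54e-06 and 7.93e-05, adjusted p = 0.201 and 0.203 with an estimated correlation). MHC class I had 0.37 and 0.39 (adjusted p = 4.59e-05 and 2.27e-07, adjusted p = 0.229 and 0.175 with an estimated correlation). Chemokines had 0.24 and 0.23 (adjusted p = 4.94e-05 and 0.000101, adjusted p = 0.229 and 0.227 with an estimated correlation). Complement had 0.33 and 0.28 (adjusted p = 0.000456 and 0.000101, adjusted p = 0.218 and 0.175 with an estimated correlation). Urothelial genes, a measure of pelvis lining in the sample, had 0.38 and 0.69 (adjusted p = 0.00976 and 1.85e-09, adjusted p = 0.598 and 0.175 with an estimated correlation), with Upk1b (1.12 ± 0.44) highest at day 28. At day 10 podocyte (median 0.22, adjusted p = 0.00105, adjusted p = 0.534 with an estimated correlation), endothelial (median 0.25, adjusted p = 0.00931, adjusted p = 0.663 with an estimated correlation) and red blood cell genes (median 0.33, adjusted p = 0.0431, adjusted p = 0.534 with an estimated correlation) were also higher and fatty acid oxidation genes lower (median -0.10, adjusted p = 0.0337, adjusted p = 0.663 with an estimated correlation), and at day 28 immediate-early genes were higher. The immediate-early median was 0.14 (adjusted p = 0.00303, adjusted p = 0.586 with an estimated correlation). Citric acid cycle and respiratory chain genes were lower at both, with medians of -0.12 and -0.11 (adjusted p = 0.000139 and 0.0375, adjusted p = 0.534 and 0.836 with an estimated correlation). Median and mean differed in sign for the neutrophil, fat, p53 and renin-angiotensin lists at day 10 and for the distal segment and podocyte lists at day 28. Within the only scan day with more than 1 obstructed array at day 10 (3 obstructed, 2 sham), the matrix median was 0.43 and that of interferon genes 0.45.

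After 5 days of obstruction (6 obstructed, 5 sham at release) the same question was asked. Complement C3 rose most (6.54 ± 0.55), followed by Krt20 (6.07 ± 0.55), Sprr2f (4.98 ± 0.55), Vcam1 (4.84 ± 0.35), Spp1 (4.49 ± 0.44) and Lgi2 (4.48 ± 0.34). Scar matrix genes rose: Col1a1 (3.07 ± 0.32), Col3a1 (2.85 ± 0.33), Timp1 (3.28 ± 0.28) and the myofibroblast actin Acta2 (0.89 ± 0.20), with Fn1 not passing (0.46 ± 0.20). Lcn2 (3.71 ± 0.37) and Cd68 (1.09 ± 0.25) rose, and Havcr1 did not pass (1.33 ± 0.77). Lower were Ces1g (-3.86 ± 0.67), Cidea (-3.80 ± 1.29), Kcnt1 (-3.46 ± 0.50), Inmt (-2.88 ± 0.67) and Slc4a1 (-2.54 ± 0.33). Parvalbumin (Pvalb) of the distal convoluted tubule was at least 11.8-fold lower, being above background on 0 of 6 obstructed arrays. Egf (-2.38 ± 0.27) and Aqp2 (-0.98 ± 0.22) fell, and Umod (-0.19 ± 0.36), Slc34a1 (-0.45 ± 0.26), Slc22a6 (-0.31 ± 0.39) and Kl (-0.78 ± 0.36) did not pass.

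In all, 2939 rose and 2915 fell, 828 and 478 of them at least 2-fold. Without the weak arrays (none in these groups) the counts were 3410 and 3658. With slide as a random block 3561 rose and 3694 fell, and median centring gave 1791 and 292. Within the 2 scan days with both groups 2682 and 2489 rose and 2817 and 1993 fell.

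Of the lists 14 were higher and 6 lower, 6 and 1 of them also with an estimated correlation. Macrophage and monocyte genes were highest: 19 of 24 rose and 5 did not pass, with Ccr2 (3.53 ± 0.27), Lyz2 (3.43 ± 0.40) and Mrc1 (3.31 ± 0.26). Their median was 2.05 (adjusted p = 1.87e-21). Among injury genes 18 of 22 rose and 4 did not pass (median 1.68, adjusted p = 1.02e-20), with Krt20, Vcam1, Spp1 and Lcn2 the largest. Antigen presentation rose in full. For MHC class II 11 of 11 rose, with Ctss (3.55 ± 0.33) and Cd74 (2.84 ± 0.23) (median 1.64, adjusted p = 1.62e-13). For MHC class I 10 of 10 rose, with Psmb8 (2.01 ± 0.23) and H2-K1 (1.87 ± 0.18). Their median was 1.32 (adjusted p = 1.51e-11). Among chemokines 22 of 31 rose, 1 fell (23 and 1 in-list) and 8 did not pass, with Cxcl10 (3.88 ± 0.31), Cxcl1 (3.75 ± 0.37) and Ccl5 (3.41 ± 0.23). Their median was 1.15 (adjusted p = 5.62e-15). Among complement genes 13 of 19 rose, 1 fell and 5 did not pass, with Cfi (3.23 ± 0.59) and C1qb (2.16 ± 0.29) beside C3. Their median was 1.27 (adjusted p = 2.25e-08).

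Among extracellular matrix genes 23 of 30 rose (28 in-list) and 7 did not pass, with Mmp14 (2.27 ± 0.22) beside the collagens. Their median was 1.55 (adjusted p = 2.98e-18, adjusted p = 0.0522 with an estimated correlation). Among fibroblast and myofibroblast genes 13 of 18 rose and 5 did not pass, with Thy1 (2.17 ± 0.20) and Pdgfrb (1.98 ± 0.25). Their median was 0.83 (adjusted p = 1.44e-07, adjusted p = 0.0572 with an estimated correlation). For interferon response 19 of 26 rose and 7 did not pass (Oas2 1.93 ± 0.21, Gbp2 1.81 ± 0.23; median 0.88, adjusted p = 6.91e-10, adjusted p = 0.0979 with an estimated correlation). For immediate-early genes 13 of 20 rose (13 rose and 1 fell in-list) and 7 did not pass (Egr2 3.04 ± 0.35, Klf6 2.29 ± 0.20; median 1.11, adjusted p = 1.57e-09, adjusted p = 0.0522 with an estimated correlation). Among T and NK cell genes 10 of 21 rose, 2 fell and 9 did not pass (Klrd1 2.26 ± 0.17, Cd3d 1.87 ± 0.27; median 0.35, adjusted p = 0.000254, adjusted p = 0.0979 with an estimated correlation). Among neutrophil genes 7 of 14 rose (8 in-list) and 7 did not pass (S100a9 2.14 ± 0.80; median 0.45, adjusted p = 0.000485, adjusted p = 0.254 with an estimated correlation). Among urothelial genes 8 of 15 rose and 7 did not pass (Krt19 2.33 ± 0.38, Krt14 1.90 ± 0.21; median 0.97, adjusted p = 0.000485, adjusted p = 0.383 with an estimated correlation). Among cell cycle genes 7 of 33 rose, 1 fell (6 and 1 in-list), with Kif20a (0.97 ± 0.28) and Mki67 (0.91 ± 0.28). Their median was 0.27 (adjusted p = 0.0416, adjusted p = 0.785 with an estimated correlation). Without the weak arrays 14 rose.

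All measured genes of the citric acid cycle and respiratory chain fell (32 of 32), with Suclg1 (-1.38 ± 0.26) and the respiratory complex genes Sdhb (-1.33 ± 0.24) and Uqcrfs1 (-1.29 ± 0.13). Their median was -0.97 (adjusted p = 6e-26). Among fatty acid oxidation genes 24 of 30 fell (26 in-list) and 6 did not pass, with Acaa2 (-1.78 ± 0.21) and Acadm (-1.66 ± 0.23). Their median was -0.91 (adjusted p = 1.66e-12, adjusted p = 0.0522 with an estimated correlation). Among proximal tubule genes 10 of 31 fell (11 in-list), with Slc6a19 (-2.39 ± 0.56) and Slc22a8 (-1.95 ± 0.35). Their median was -0.80 (adjusted p = 5.34e-05, adjusted p = 0.31 with an estimated correlation). Without the weak arrays 25 fell. In the distal convoluted and connecting tubule 2 of 16 rose, 9 fell (2 and 12 in-list) and 5 did not pass (Slc16a7 -2.38 ± 0.45, S100g -1.99 ± 0.23; median -0.87, adjusted p = 0.000289, adjusted p = 0.254 with an estimated correlation). Among intercalated cell genes 9 of 17 fell and 8 did not pass (Rhbg -1.63 ± 0.37; median -0.70, adjusted p = 0.00139, adjusted p = 0.47 with an estimated correlation). In the thick ascending limb 1 of 17 rose, 6 fell and 10 did not pass (Slc12a1 -1.69 ± 0.46; median -0.61, adjusted p = 0.0453, adjusted p = 0.515 with an estimated correlation).

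Not called were principal cell (3 of 18 fell), podocyte (4 of 18 rose, with median and mean of different sign), endothelium (1 of 20 fell), smooth muscle (4 of 12 rose), B and plasma cell (2 of 17 rose), perirenal fat (1 of 13 fell), adrenal gland (0 of 12 passed), red blood cell (1 rose and 1 fell of 6), p53 (5 rose and 2 fell of 19), hypoxia (3 rose and 5 fell of 18), NRF2 (3 rose and 5 fell of 19), renin-angiotensin (1 rose and 2 fell of 10) and sex-linked transcripts (0 of 5 passed). Without the weak arrays principal cell genes were lower (6 of 18 fell, adjusted p = 0.0108). Within the 2 scan days with both groups the macrophage medians were 1.96 and 2.19, injury 1.96 and 1.66, matrix 1.43 and 1.56, and respiratory -1.07 and -0.86.

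At 10 days after release of the 5-day clamp (8 obstructed, 6 sham) macrophage genes were in front. The lysozymes Lyz2 (4.09 ± 0.35) and Lyz1 (4.01 ± 0.34) rose most, followed by C3 (3.96 ± 0.49), Vcam1 (3.93 ± 0.32), Sprr2f (3.71 ± 0.49) and Aoc1 (3.69 ± 0.56). Injury and scar genes remained above sham: Lcn2 (2.74 ± 0.33), Spp1 (2.40 ± 0.39), Col1a1 (2.58 ± 0.29), Col3a1 (2.43 ± 0.29), Timp1 (2.29 ± 0.25), Fn1 (0.66 ± 0.17), Acta2 (0.65 ± 0.18) and Cd68 (1.01 ± 0.23). Pvalb (-2.84 ± 0.34), Kcnt1 (-2.12 ± 0.45), Rhox6 (-1.96 ± 0.39) and Hpd (-1.88 ± 0.61) were lower. So were F13b (-1.80 ± 0.51), Cwh43 (-1.74 ± 0.43) and Egf (-1.03 ± 0.24). Havcr1 (1.07 ± 0.68), Umod (-0.044 ± 0.32), Slc34a1 (-0.25 ± 0.23), Slc22a6 (-0.21 ± 0.35), Aqp2 (-0.17 ± 0.20) and Kl (-0.50 ± 0.32) did not pass.

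Here 2423 genes rose and 2182 fell, 600 and 1.1e+02 of them at least 2-fold. Of them 1971 had risen and 1724 had fallen at release too (380 and 340 expected by chance), and 1 had gone the opposite way. Without the weak arrays the counts were 3026 and 3026, with slide as a random block 2240 and 1968, and with median centring 931 and 120. On the only scan day with both groups (2 obstructed, 6 sham) 1989 rose and 1460 fell, and the macrophage, injury, matrix and respiratory medians were 1.90, 1.46, 1.14 and -0.66.

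Again 14 lists were higher and 6 lower, and with an estimated correlation 9 and 3. Among macrophage genes 18 of 24 rose (19 in-list) and 6 did not pass, with Ms4a7 (3.23 ± 0.31), Adgre1 (2.61 ± 0.31) and Trem2 (2.55 ± 0.33). Their median was 2.00 (adjusted p = 4.63e-25). Among injury genes 17 of 22 rose (18 in-list) and 5 did not pass. Their median was 1.36 (adjusted p = 1.05e-16). Among matrix genes 27 of 30 rose and 3 did not pass, with Mmp14 (2.13 ± 0.20). Their median was 1.27 (adjusted p = 1.05e-22). Among fibroblast genes 13 of 18 rose (14 in-list) and 5 did not pass (Mfap4 2.62 ± 0.27, Thy1 1.68 ± 0.18; median 0.83, adjusted p = 1.17e-09). Among complement genes 13 of 19 rose (14 rose and 1 fell in-list) and 6 did not pass (C1qb 2.16 ± 0.26, Cfi 2.07 ± 0.52; median 1.22, adjusted p = 1.57e-10). Among chemokines 21 of 31 rose (23 in-list) and 10 did not pass, with Ccl8 (2.99 ± 0.38), Ccl6 (2.69 ± 0.33) and Ccl9 (2.55 ± 0.25). Their median was 0.86 (adjusted p = 4.4e-15). For MHC class II 9 of 11 rose (10 in-list) and 2 did not pass (Ctss 3.37 ± 0.29, Cd74 2.36 ± 0.20; median 1.33, adjusted p = 5.79e-14). For MHC class I 10 of 10 rose. Their median was 1.03 (adjusted p = 1.15e-11). Among T and NK cell genes 12 of 21 rose, 1 fell (13 and 1 in-list) and 8 did not pass (Cd3d 1.99 ± 0.24, Cxcr6 1.72 ± 0.23; median 0.45, adjusted p = 4.08e-07).

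Among urothelial genes 10 of 15 rose (12 in-list) and 5 did not pass (Krt19 2.06 ± 0.34, Upk1b 1.84 ± 0.41; median 1.16, adjusted p = 4.08e-07, adjusted p = 0.147 with an estimated correlation). Of the interferon response genes 17 of 26 rose and 9 did not pass (median 0.59, adjusted p = 1.95e-08, adjusted p = 0.133 with an estimated correlation). Among immediate-early genes 10 of 20 rose, 1 fell (12 and 1 in-list) and 9 did not pass (Egr2 2.50 ± 0.31; median 0.52, adjusted p = 1.62e-06, adjusted p = 0.133 with an estimated correlation). Among cell cycle genes 8 of 33 rose, 1 fell (10 and 1 in-list) and 24 did not pass (Mki67 0.94 ± 0.25; median 0.40, adjusted p = 0.00154, adjusted p = 0.587 with an estimated correlation), and among neutrophil genes 4 of 14 rose and 10 did not pass (median 0.14, adjusted p = 0.0133, adjusted p = 0.441 with an estimated correlation). Among citric acid cycle and respiratory chain genes 30 of 32 fell (31 in-list) and 2 did not pass (Sdhb -1.02 ± 0.22, Uqcrfs1 -0.98 ± 0.12; median -0.64, adjusted p = 1.61e-22). Among fatty acid oxidation genes 21 of 30 fell (28 in-list) and 9 did not pass (median -0.64, adjusted p = 6.67e-12). Among NRF2 and antioxidant genes 1 of 19 rose, 7 fell and 11 did not pass (Cat -1.04 ± 0.19, Sod1 -0.73 ± 0.12; median -0.35, adjusted p = 0.00442). In the proximal tubule 7 of 31 fell (10 in-list) and 24 did not pass (Slc6a19 -1.45 ± 0.50; median -0.58, adjusted p = 7.71e-05, adjusted p = 0.333 with an estimated correlation). In the distal convoluted tubule 5 of 16 fell and 11 did not pass (median -0.48, adjusted p = 0.00337, adjusted p = 0.362 with an estimated correlation), and in the thick ascending limb 3 of 17 fell and 14 did not pass (Ptger3 -1.24 ± 0.44; median -0.41, adjusted p = 0.0119, adjusted p = 0.396 with an estimated correlation). Not called were principal cell (0 of 18 passed), intercalated cell (2 of 17 fell), podocyte (5 of 18 rose), endothelium (1 of 20 rose), smooth muscle (3 of 12 rose), B cell (3 of 17 rose), p53 (4 rose and 1 fell of 19) and hypoxia genes (4 of 18 fell).

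At 28 days after release of the 5-day clamp (5 obstructed, 6 sham) the highest genes were immune ones. Lyz2 (2.78 ± 0.40), Lyz1 (2.47 ± 0.38), Vcam1 (2.40 ± 0.35), Ms4a7 (2.34 ± 0.35), C3 (2.10 ± 0.55) and the cathepsin Ctss (1.98 ± 0.33) rose most. Lcn2 (1.29 ± 0.37), Col1a1 (1.51 ± 0.32) and Col3a1 (1.4 ± 0.33) were still higher. The lowest genes included the circadian clock outputs Dbp (-1.66 ± 0.43), Tef (-1.08 ± 0.25) and Per2 (-1.23 ± 0.33), with Ak4 (-1.05 ± 0.30), Rufy3 (-1.02 ± 0.27) and Coq10b (-1.02 ± 0.23). The rest of the panel did not pass: Spp1 (1.12 ± 0.44), Timp1 (0.87 ± 0.28), Havcr1 (-0.16 ± 0.77), Fn1 (-0.055 ± 0.20), Acta2 (0.19 ± 0.20), Cd68 (0.38 ± 0.25), Egf (0.14 ± 0.27), Aqp2 (0.12 ± 0.22), Umod (0.87 ± 0.36), Slc34a1 (0.50 ± 0.26), Slc22a6 (0.39 ± 0.39) and Kl (-0.12 ± 0.36).

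The count was 437 higher and 93 lower, 128 and 7 at least 2-fold, and 429 and 78 of them had gone the same way at day 10 (56.6 and 10.8 expected by chance). It depended on the model: 907 and 404 without the weak arrays, 11 and 0 with slide as a random block, 74 and 1 with scan day as a fixed term and 155 and 2 with median centring. Leaving out 1 array gave 166 to 980 genes.

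Among the lists 12 were higher and 2 lower, and 5 higher with an estimated correlation. Among macrophage genes 13 of 24 rose (15 in-list) and 11 did not pass (Trem2 1.76 ± 0.37, Adgre1 1.72 ± 0.35; median 0.94, adjusted p = 2.04e-20). Among MHC class II genes 7 of 11 rose (9 in-list) and 4 did not pass (Cd74 1.46 ± 0.23; median 0.97, adjusted p = 7.31e-14). Among complement genes 6 of 19 rose (11 in-list) and 13 did not pass (median 0.74, adjusted p = 3.03e-09). Among chemokines 7 of 31 rose (12 in-list) and 24 did not pass (Ccl8 2.02 ± 0.42, Ccl12 1.70 ± 0.31; median 0.53, adjusted p = 1.82e-11). Among injury genes 9 of 22 rose (12 in-list) and 13 did not pass (Krt20 1.84 ± 0.55, Sox9 1.14 ± 0.32; median 0.64, adjusted p = 3.16e-11). The others were called at the preset correlation only. Among matrix genes 6 of 30 rose (16 in-list) and 24 did not pass (Dcn 1.37 ± 0.29; median 0.48, adjusted p = 7.78e-12, adjusted p = 0.151 with an estimated correlation). Among fibroblast genes 3 of 18 rose (8 in-list) and 15 did not pass (Mfap4 1.51 ± 0.30; median 0.51, adjusted p = 1.16e-07, adjusted p = 0.0928 with an estimated correlation). Among T and NK cell genes 4 of 21 rose (6 in-list) and 17 did not pass (Cd3d 1.32 ± 0.27; median 0.20, adjusted p = 0.000134, adjusted p = 0.128 with an estimated correlation). Among MHC class I genes 2 of 10 rose (6 in-list) and 8 did not pass (median 0.48, adjusted p = 1.19e-05, adjusted p = 0.162 with an estimated correlation), and among interferon genes 1 of 26 rose and 25 did not pass (median 0.32, adjusted p = 1.19e-05, adjusted p = 0.32 with an estimated correlation). Among urothelial genes 1 of 15 rose (9 in-list) and 14 did not pass (median 0.76, adjusted p = 9.92e-07, adjusted p = 0.198 with an estimated correlation), and among immediate-early genes 3 of 20 rose (4 in-list) and 17 did not pass (median 0.24, adjusted p = 0.000414, adjusted p = 0.33 with an estimated correlation). Among respiratory chain genes 3 of 32 fell (10 in-list) and 29 did not pass (Uqcrfs1 -0.50 ± 0.13; median -0.29, adjusted p = 8.59e-14, adjusted p = 0.0978 with an estimated correlation), and among fatty acid oxidation genes 1 of 30 fell and 29 did not pass (Acads -0.89 ± 0.25; median -0.20, adjusted p = 0.000108, adjusted p = 0.356 with an estimated correlation). No nephron segment list was called: the medians were 0.0064 (proximal), -0.038 (thick ascending limb), -0.12 (distal convoluted), -0.003 (principal cell) and -0.14 (intercalated cell).

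**Figure D2:**
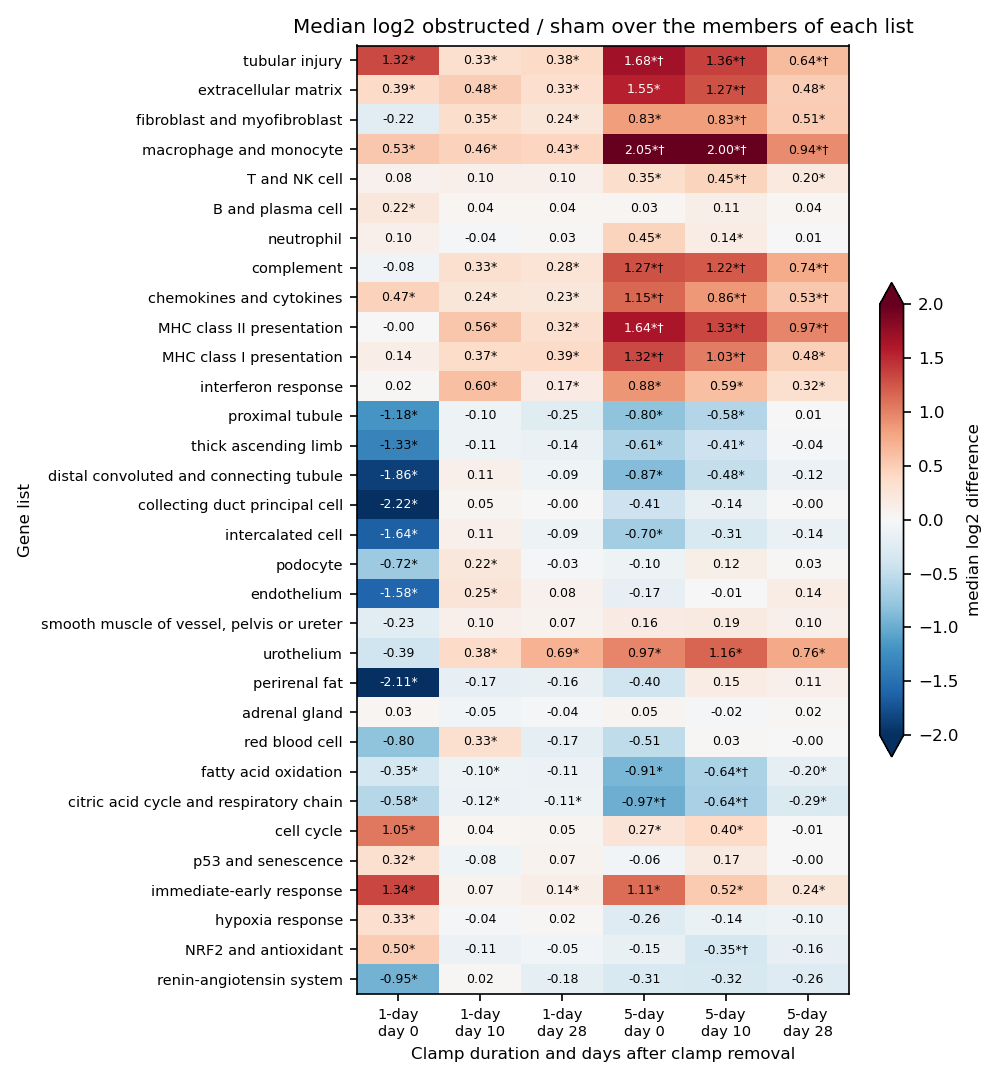
Median log2 difference between obstructed and sham of each gene list (rows) in the 6 comparisons (columns). A star marks a camera call and a dagger one that holds with an estimated correlation.

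**Figure D3:**
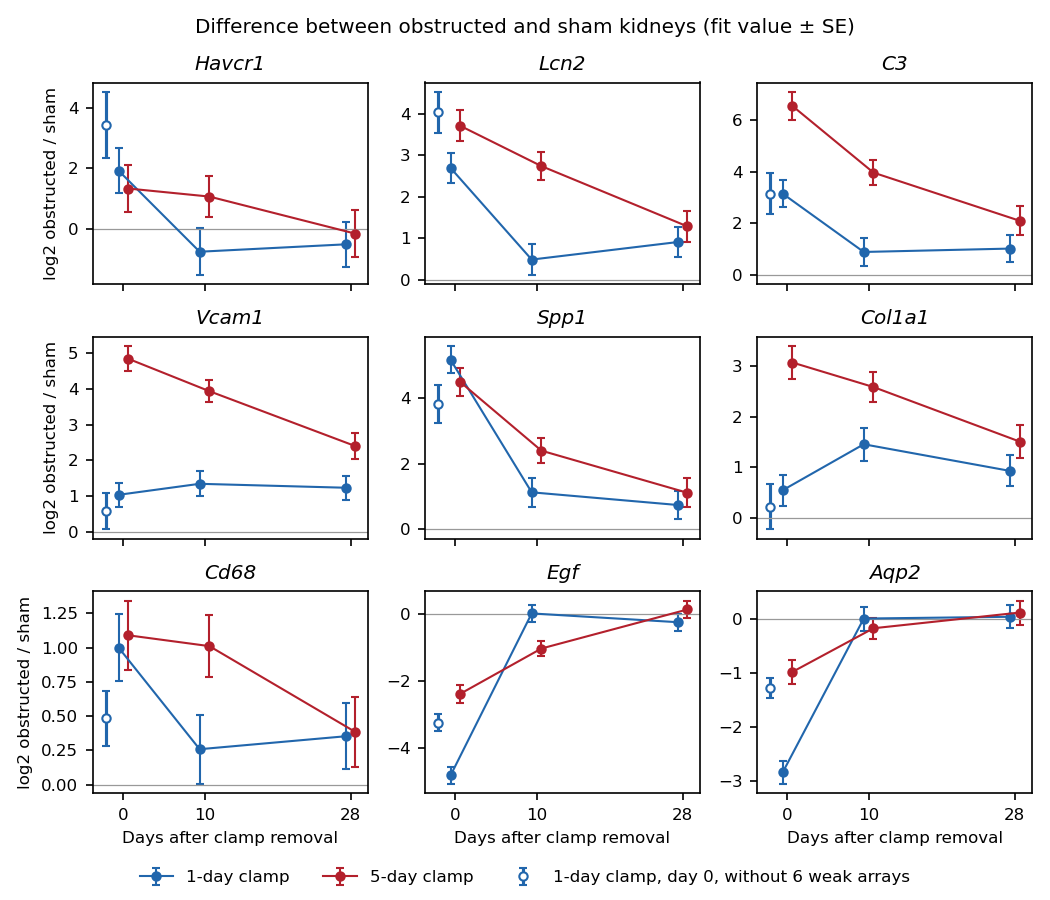
Log2 difference between obstructed and sham (± SE) of 9 genes by days after clamp removal, for the 1-day and 5-day clamps. Open symbols leave out the 6 weak arrays.

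The effect of the clamp's duration was tested as the 5-day minus the 1-day difference from sham. At release 2048 genes had a higher and 1387 a lower 5-day effect (1859 and 954 without the weak arrays, 6730 and 1098 with median centring). Largest were Aoc1 (5.00 ± 0.87), Mgp (4.06 ± 0.51), Mrc1 (3.92 ± 0.36), Cck (3.87 ± 0.66) and Ubd (3.83 ± 0.53). Vcam1 (3.80 ± 0.49), C3 (3.39 ± 0.76), Col1a1 (2.52 ± 0.45) and Egf (2.44 ± 0.37) were higher too. Fgg (-3.65 ± 0.56), Ces1g (-3.11 ± 0.93), Mt2 (-2.37 ± 0.40), Angptl4 (-2.22 ± 0.70) and Ifi202b (-2.2 ± 0.73) were lowest. Median centring, which moved the median of all genes by 0.71, turned Mt2 to 0.085. Endothelial genes had a higher 5-day effect (median 1.60, adjusted p = 1.54e-10, adjusted p = 0.141 with an estimated correlation), cell cycle genes a lower one (median -0.72, adjusted p = 3.6e-09, adjusted p = 0.238 with an estimated correlation) and NRF2 genes a lower one. The NRF2 median was -0.62 (adjusted p = 2.58e-05). These 3 medians were 0.80, -0.24 and -0.42 without the weak arrays, and Aoc1 was 2.82, Cck 2.25 and Fgg -2.47, while Egf (0.86) and Ifi202b (-0.45) no longer passed. Of the injury markers, Vcam1 separated the clamps at release but 3 others did not pass: Lcn2 differed by 1.01 ± 0.51, Spp1 by -0.68 ± 0.60 and Havcr1 by -0.59 ± 1.06 (-0.33, 0.66 and -2.10 without the weak arrays).

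At day 10, 457 genes had a higher and 242 a lower 5-day effect (792 and 648 without the weak arrays, 91 and 3 with median centring). The 5-day excess was in Lyz1 (3.1 ± 0.51), C3 (3.07 ± 0.74), Rnase2a (3.01 ± 0.37), Lyz2 (2.97 ± 0.53), Vcam1 (2.59 ± 0.47), Lcn2 (2.25 ± 0.50) and Timp1 (1.59 ± 0.37). Pvalb (-3.05 ± 0.51), Dpys (-1.87 ± 0.48), Cox7a1 (-1.69 ± 0.37), Acsl1 (-1.45 ± 0.38) and Acss1 (-1.44 ± 0.41) were lower. Col1a1 did not separate the clamps (1.13 ± 0.43, adjusted p = 0.147). Macrophage (median 1.20, adjusted p = 5.69e-23), injury (median 1.0, adjusted p = 8.72e-15) and MHC class II genes (median 0.97, adjusted p = 1.9e-10) were higher, and respiratory chain genes lower. The respiratory median was -0.49 (adjusted p = 2.94e-19). At day 28 limma called 0 genes (1269 at unadjusted p under 0.05), so that the 530 genes of the 5-day clamp and the single gene of the 1-day clamp were not shown to differ.

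Recovery was tested as the change of the difference from sham between collection days. From day 0 to day 10 after the 1-day clamp 2216 genes went up and 1395 down relative to sham (1795 and 973 without the weak arrays, 1127 and 100 with median centring). Genes that went up included Slc12a1 (4.92 ± 0.63), Egf (4.85 ± 0.37), Wfdc15b (4.77 ± 0.58), Cck (4.38 ± 0.66), Aldh1a3 (4.38 ± 1.49) and Aqp2 (2.85 ± 0.31). Fgg (-6.16 ± 0.56), Spp1 (-4.04 ± 0.60), Fgb (-3.68 ± 0.59), Saa2 (-3.54 ± 0.38) and Lrg1 (-3.41 ± 0.44) went down. Endothelial (median 1.95, adjusted p = 3.07e-15, adjusted p = 0.0878 with an estimated correlation) and principal cell genes (median 2.12, adjusted p = 8.53e-12, adjusted p = 0.0878 with an estimated correlation) went up, and cell cycle genes down. The cell cycle median was -1.01 (adjusted p = 4.43e-14, adjusted p = 0.197 with an estimated correlation). These 3 medians were 1.25, 1.21 and -0.53 without the weak arrays, and Slc12a1 was 2.67, Egf 3.27, Wfdc15b 1.82, Cck 2.76, Aqp2 1.28, Fgg -4.97 and Spp1 -2.70, while Aldh1a3 no longer passed. From day 10 to day 28 limma called 0 genes (1292 at unadjusted p under 0.05).

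After the 5-day clamp only 22 genes went up and 83 down between day 0 and day 10 (98 and 184 without the weak arrays, 25 and 39 with the scanner software's log ratio, 2 and 57 with median centring). Spt2 (2.14 ± 0.29), Slc4a1 (1.76 ± 0.45), the eosinophil ribonucleases Rnase2a (1.53 ± 0.37) and Ear1 (1.08 ± 0.28), and Omd (1.17 ± 0.28) went up. Saa2 (-2.61 ± 0.37), Fgb (-2.30 ± 0.57), Cxcl10 (-2.13 ± 0.41), Tfr2 (-1.77 ± 0.26) and Ccl5 (-1.74 ± 0.31) went down, as did the injury list. Its median was -0.76 (adjusted p = 1.62e-11). Between day 10 and day 28, 0 genes went up and 9 down (65 and 124 without the weak arrays, 14 and 48 with the scanner software's log ratio), among them Rnase2a (-1.96 ± 0.37), Ear1 (-1.88 ± 0.28), Spt2 (-1.58 ± 0.29), D17H6S56E-5 (-1.34 ± 0.28) and Ear10 (-1.22 ± 0.22). Proximal tubule (median 0.60, adjusted p = 1.29e-07, adjusted p = 0.172 with an estimated correlation) and respiratory chain genes (median 0.30, adjusted p = 3.23e-14, adjusted p = 0.083 with an estimated correlation) went up, and matrix (median -0.69, adjusted p = 4.81e-17, adjusted p = 0.083 with an estimated correlation), macrophage (median -0.79, adjusted p = 3.68e-15, adjusted p = 0.0626 with an estimated correlation) and injury genes (median -0.68, adjusted p = 6.18e-11, adjusted p = 0.052 with an estimated correlation) down, at the preset correlation only.

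All 36 obstructed arrays against all 35 sham arrays, averaged over clamps and days, gave 4075 genes higher and 4758 lower (3927 and 4567 without the weak arrays, 1887 and 3844 with median centring). C3 (2.94 ± 0.22), Krt20 (2.85 ± 0.22), Sprr2f (2.67 ± 0.22), Spp1 (2.51 ± 0.17) and Vcam1 (2.46 ± 0.14) rose most, and Pvalb (-1.80 ± 0.15), Kcnt1 (-1.75 ± 0.20), Ucp1 (-1.55 ± 0.52), Sucnr1 (-1.53 ± 0.25) and Slc16a7 (-1.45 ± 0.18) fell most. All 32 respiratory chain genes were lower, and injury, matrix, macrophage, complement, chemokine, MHC class I, MHC class II and immediate-early lists were higher, all also with an estimated correlation. The 1-day and 5-day effects at release shared 1185 higher and 1650 lower genes (516 and 612 expected by chance), and 8.75% of the genes called in both had opposite directions.

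Shams of day 0 (11 arrays) differed from the 4 normal controls in 533 higher and 1033 lower genes (1112 and 2212 without the weak arrays, 24 and 60 with slide as a random block, 1522 and 2224 with median centring, 743 and 935 with the scanner software's log ratio). Leaving out 1 normal control gave 395 to 2554 genes. Ptprz1 (2.27 ± 0.30), Pigt (1.78 ± 0.30), the stress gene Ndrg1 (1.61 ± 0.24), granulin (Grn, 1.53 ± 0.23) and Syt10 (1.4 ± 0.21) were higher. Smcp (-2.90 ± 0.53), C1qtnf3 (-2.48 ± 0.63), Kif20b (-2.44 ± 0.68), Ugt8a (-2.24 ± 0.70) and Chrm1 (-2.2 ± 0.44) were lower. No panel gene passed. MHC class I genes were higher (median 0.39, adjusted p = 0.0206, adjusted p = 0.905 with an estimated correlation) and cell cycle genes lower. The cell cycle median was -0.32 (adjusted p = 0.0391, adjusted p = 0.905 with an estimated correlation). Scan day and group coincide here, so surgery and batch cannot be told apart. All 4 normal controls were low in Xist, a transcript of females, as were 6 of the 11 shams.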

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

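The splits into other groups and the tests of the weak arrays were chosen only after the results were seen. The tests of scan day and time of day were written before their result was known.

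Several genes and lists had 1 array apart from its group by a gap of most of the group's range. Of 676 tests (52 measures in 13 groups) 47 stood out this way, and chance alone marks about 1 in 20 groups, so isolated ones carry little weight. Values are log2 ratios to the reference, or their means over a list.

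Injury genes were high on obstructed replicate 10 of the 1-day clamp at day 10: Havcr1 2.15 (the others 0.694 to 0.982), Lcn2 1.68 (-0.771 to -0.367), Spp1 1.89 (-0.217 to 0.115) and Timp1 -1.77 (-3.4 to -3.05). The same kidney was low in thick ascending limb genes at 3.06 (3.4 to 3.54), fatty acid oxidation genes at 2.34 (2.81 to 2.97), NRF2 genes at 1.32 (1.6 to 1.67) and adrenal genes at 0.0802 (0.318 to 0.394). Normal control replicate 4 stood apart with C3 at -1.8 (-3.31 to -3.23), Fn1 -3.23, Egf 5.65 (6.65 to 6.78), Slc34a1 7.13 (8.31 to 8.38), proximal tubule genes 5.3 (6.32 to 6.48), intercalated cell genes 2.82, NRF2 genes 1.4 and sex-linked transcripts -0.15. It had its own slide and scan day and reference signal 184 (372 to 390), so batch stays open. Obstructed replicate 20 of the 5-day clamp at day 0 had less scar-matrix signal: Col1a1 -1.8 (-0.524 to 0.193), Col3a1 -1.59, Acta2 -1.33 and interferon genes -0.0807, with fatty acid oxidation genes at 2.64 (1.89 to 2.16). Obstructed replicate 33 of the 5-day clamp at day 28 had Vcam1 at -2.02 (0.379 to 1.23) and T and NK cell genes at -0.0296 (0.39 to 0.561).

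Other arrays stood out in 1 to 3 measures. Among obstructed arrays these were neutrophil genes 0.938 and hypoxia genes -1.12 (5-day, day 0, replicate 22), Cd68 -1.5 and adrenal genes 0.579 (1-day, day 28, replicate 15), perirenal fat genes 1.24 (5-day, day 10, replicate 28) and sex-linked transcripts -1.06 (1-day, day 0, replicate 6). Among shams of the 1-day clamp they were Egf 6.64 (day 0, replicate 6), Lcn2 0.676 and neutrophil genes 1.69 (day 10, replicate 14), adrenal genes 1.44 (day 10, replicate 11) and, at day 28, Slc22a6 1.26 against 4.5 to 5.06 (replicate 17), adrenal genes 0.535 and p53 genes -0.971 (replicate 21) and 65.2% of probes above background (replicate 22). Among shams of the 5-day clamp they were, at day 0, Spp1 -0.21 and sex-linked transcripts -1.23 (replicate 24) and endothelial genes 3.6 (replicate 26). At day 10 they were Umod 6.22, Egf 6.68 and respiratory chain genes 1.44 (replicate 28), Timp1 -3.72 (replicate 33) and adrenal genes 0.343 (replicate 29), and at day 28 Umod 5.07 and Egf 5.83 (replicate 39).

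The effects of obstruction differed between groups in 3435 genes by clamp duration at day 0 and 699 at day 10, and in 3611 genes between day 0 and day 10 of the 1-day clamp, 105 of the 5-day clamp, and 9 between its days 10 and 28. Probes without a gene symbol, 5558 of them, were not in any comparison: 938 passed for the 1-day clamp at day 0, 680, 348 and 21 for the 5-day clamp at days 0, 10 and 28, and 0 in the others.

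Up to 100 splits of the same arrays into groups of the same sizes were compared with the real one, counted among them. Batch aside, chance is unlikely for the 5-day clamp at day 0 (5854 genes, 1 split as large, highest other 4186), day 10 (4605, 1 split, 3638) and day 28 (530, 1 split, 2.0e+02). So it is for all obstructed against all sham (8833, 1 split, 5) and the duration difference at day 10 (699, 1 split, 1). Another split exceeded the 5-day change from day 0 to 10 (105, 2 splits, 2.0e+02). The counts of the 5-day change from day 10 to 28 (9 genes, 2 splits, 15) and the 1-day clamp at day 28 (1 gene, 3 splits, 2747) are too small to rest anything on, as some settings gave 0 for each. Chance could not be excluded for the 1-day clamp at day 0 (7216, 10 splits, 9344) or day 10 (5, 29 splits, 1412), the duration differences at day 0 (3435, 8 splits, 8417) and day 28 (0, 100 splits, 237), the 1-day changes from day 0 to 10 (3611, 9 splits, 8393) and day 10 to 28 (0, 100 splits, 844), or sham against normal control (1566, 8 splits, 4007). Some splits called many times the real count (2747 against 1), which points to other sample structure. Xist (below) is an untested candidate. The splits ignore slides and scan days, within which arrays correlate (0.399 and 0.4), so they do not allow for batch.

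The broad decrease after the 1-day clamp at day 0 might be due to the weak arrays, as 4 of its 6 obstructed arrays are weak. Without them the endothelial median was -1.06 (-1.58 with them) and the injury median 1.23 (1.32), and both of the obstructed arrays left lay on that side of the sham mean. Weak signal was thus not needed for shifts of this sign. For the proximal tubule, matrix, fatty acid oxidation, renin-angiotensin and hypoxia lists it remains a candidate, since their medians without the weak arrays were -0.15, -0.18, -0.083, -0.0077 and -0.051. The B cell and p53 lists lost their calls too (adjusted p = 0.373 and 0.0885). With 2 obstructed arrays left, on slides without shams, chance and batch are not excluded.

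The clock genes that were lower after the 5-day clamp at day 28 could follow from another time of day at collection. Genes that peak in the opposite phase were higher by 0.389 ± 0.0738 in the mean (exact permutation p = 0.00649, 0.0195 adjusted over the 12 tests), as another hour would predict. Their median was 0.132 (0.144 with scan day as a fixed term) and 1 of 5 passed, so few genes made the mean. Dbp-phase genes, a list written around genes already seen to be lower here, were at -0.806 ± 0.134 in the mean. Their median was -0.853, and -0.737 with scan day as a fixed term. That term rests on 3 arrays that link the scan days, so scan day is made less likely but is not excluded. At day 0 of the 1-day and 5-day clamps the Dbp-phase genes were lower by -0.635 and -0.697. The opposite phase was at 0.17 and -0.0648 there and did not pass. At day 10 of the 5-day clamp both moved, by -0.774 (0 of 8 arrays above the sham mean) and 0.28 (8 of 8, exact permutation p = 0.000666, 0.004 adjusted, median 0.0128). Whether obstruction changed the clock stays open, as the sources used give no collection hours.

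The genes called after the 5-day clamp at day 28 might be due to scan day, since no scan day held both groups. From the 64 other arrays, 3 of which link the scan days, the difference between the days was 0.132 of the effect for the 437 higher genes (-0.0456 to 0.334 leaving out each linking array) and 0.156 for the 93 lower genes (-0.0251 to 0.335). It was thus small in the median, but had the effect's sign in 312 and 68 genes. How many scan day explains stays open (75 called as a fixed term, 167 as a random block), as does slide (11 as a random block).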

How the results depend on the processing

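Some alternatives were chosen only after the data were seen: the spot's own local background, scan day as a random block, the sex-linked term, and leaving out the 6 weak arrays, alone, with an estimated correlation or with only the groups compared. The others were set beforehand. Over 851 pairs of a named gene and a comparison, the other settings gave 15042 values: 13721 kept direction and side of the threshold, 968 were weaker, 59 reversed and the rest stronger. Leaving out arrays gave 13571 values, of which 13082 stayed, 452 were weaker, 37 stronger and 0 reversed. In the comparisons of obstructed with sham, 39 of 3885 values reversed for the 1-day clamp at day 0, 1 for the 5-day clamp at day 28 and 0 in the other 4 comparisons. Except where a cause is named, the cause was not tested. A few counts are rounded to 2 digits (3.0e+02). Numbers of genes called come in this order: 1-day clamp days 0, 10 and 28 (7216, 5, 1 with the chosen settings), 5-day clamp days 0, 10 and 28 (5854, 4605, 530), duration differences at days 0, 10 and 28 (3435, 699, 0), changes from day 0 to 10 and 10 to 28 after the 1-day (3611, 0) and 5-day clamp (105, 9), all obstructed against sham (8833), and sham against normal control (1566).

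Median centring in place of loess called 12178, 0 and 0 genes for the 1-day clamp, 2083, 1051 and 1.6e+02 for the 5-day clamp, 7828 and 94 for duration at days 0 and 10, 1227 for the 1-day change to day 10, 59 and 1 for the 5-day changes, 5731 over all and 3746 against normal control, and 264 of the named values passed. It left intensity-dependent dye bias in, by construction, and the cause of each change was not tested. It reversed, for the 1-day clamp at day 0, Ankrd37 -0.1512, Cd68 -0.2243, Col1a1 -1.247, Col3a1 -1.381, Col8a1 -0.688, Egln3 -0.2275, Fn1 -0.8574, Isg15 -0.4643, Junb -0.2498, Lox -0.1371, Mgst1 -0.6638, Mzb1 -0.7066, Oasl1 -0.462, Pou2af1 -0.4724, Psmb10 -1.226, Srxn1 -0.685, Txnrd1 -0.9855 and Vcam1 -0.2211. For duration at day 0 it reversed Fn1 (1.471) and Mt2 (0.085), and over all arrays Acta2 (-0.1134) and Fn1 (-0.003041).

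Array weights for the 1-day clamp at day 0 were 0.546 to 1.61 on the 4 weak obstructed arrays and 0.0819 and 0.0858 on the other 2, and 0.115 and 0.127 on the weak shams. They called 12140, 210 and 2806 genes for the 1-day clamp, 8789, 8956 and 928 for the 5-day clamp, 9960, 4044 and 2.8e+02 for duration, 10557 and 1705 for the 1-day changes, 890 and 1780 for the 5-day changes and 6463 against normal control. Weights reversed Slc22a6 for the 1-day clamp at day 0 (0.7365), Cd68 for duration at day 0 (-0.9056) and Umod against normal control (-0.6355).

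The scanner software's log ratio and the series matrix, the same values by origin, each called 0 and 4 genes for the 1-day clamp at days 10 and 28, 1 for duration at day 28, and 64 and 62 for the 5-day changes. They reversed, for the 1-day clamp at day 0 (software, then series matrix), H2-Ab1 0.3848 and 0.382, Hbb-bt 0.7658 and 0.7751, Isg15 -0.05769 and -0.05979, Kl 0.2598 and 0.2602, Ppara 0.1029 and 0.1021, Ren1 0.1134 and 0.1218, Slc22a6 1.617 and 1.628, and Slc34a1 1.517 and 1.506. They also reversed Kl (-0.5986 and -0.6068) and Slc34a1 (-1.861 and -1.843) for duration at day 0, Kl (-0.05123 and -0.04983) and Slc34a1 (-1.624 and -1.609) for the 1-day change to day 10, and Slc34a1 over all arrays (0.1792 and 0.1797). The cause was not tested.

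Without the 6 weak arrays 3726, 69 and 2 genes were called for the 1-day clamp, 1311 for the 5-day clamp at day 28, 1440 and 5 for duration at days 10 and 28, 2.8e+02 and 189 for the 5-day changes and 3324 against normal control. With only the groups compared as well, these were 3762, 50 and 0 for the 1-day clamp, 1091 and 8 for duration, 2167 for the 1-day change to day 10, 3.0e+02 and 1.6e+02 for the 5-day changes and 4086 against normal control. Both reversed Acot12 (0.2713) and H2-Ab1 (0.0799) for the 1-day clamp at day 0 and Kl for duration at day 0 (-0.4441). Only the groups compared, with the weak arrays in, called 2103, 50 and 0 for the 1-day clamp, 1803, 1091 and 8 for duration, 1067 for the 1-day change to day 10 and 3.0e+02 and 1.6e+02 for the 5-day changes. Fewer arrays enter these models by construction.

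Slide as a random block (correlation 0.399) called 2974, 81 and 0 genes for the 1-day clamp, 11 for the 5-day clamp at day 28, 1892 for duration at day 0, 1555 for the 1-day change to day 10, 197 and 3 for the 5-day changes and 84 against normal control. As a fixed term it called 106 and 0 for the 1-day clamp at days 10 and 28, 3 for the 5-day clamp at day 28, 1 for duration at day 28, 1 for the 1-day change from day 10 to 28 and 167 for the 5-day change to day 10, and reversed Sox9 at day 28 of the 5-day clamp (-0.3672). It was not estimable for the 1-day clamp at day 0, duration at day 0, the 1-day change to day 10, all arrays and normal control. Scan day as a fixed term called 52 and 0 for the 1-day clamp at days 10 and 28, 75 for the 5-day clamp at day 28, 2132 for the 1-day change to day 10 and 37 for the 5-day change from day 10 to 28, and was not estimable for normal control. As a random block scan day called 63 and 0 (1-day, days 10 and 28), 167 (5-day, day 28), 29 (5-day change from day 10 to 28) and 18 (normal control). The cause was not tested.

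The replicate numbers of the labels do not pair obstructed with sham arrays: same-number arrays were the most alike in only 1 case. With the replicate number as a block (correlation -0.171) 0 genes were called for the 1-day clamp at day 28, and the other counts moved by less than 1.5-fold.

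The spot's own local background called 1 and 0 genes for the 1-day clamp at days 10 and 28, 280 for the 5-day clamp at day 28, 1879 for duration at day 0, 2399 for the 1-day change to day 10 and 32 and 0 for the 5-day changes. The sex-linked term called 3 (1-day, day 10), 859 (5-day, day 28), 1070 (duration, day 10) and 1.6e+02 and 30 (5-day changes). The mean of all probes of a gene called 1 and 2 (1-day, days 10 and 28) and 17 (5-day change from day 10 to 28), and reversed Slc22a6 over all arrays (-0.3462). A stricter filter on dim probes called 4 for that last change. Without a filter no count moved by more than 1.5-fold, and Aquantile leaves log ratios unchanged by construction. The cause of the others was not tested.

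With an estimated correlation 0, 0 and 0 lists were called for the 1-day clamp at days 0, 10 and 28, in place of 21, 15 and 12, and 7, 12 and 5 for the 5-day clamp, in place of 20, 20 and 14. Without the weak arrays these were 0, 0, 0, 8, 9 and 5. A larger correlation widens the test by construction.

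Leaving out 1 array at a time gave 5889 to 8460, 0 to 8 and 0 to 5 genes for the 1-day clamp, 5053 to 5810, 3899 to 4780 and 166 to 980 for the 5-day clamp, 2593 to 5031, 445 to 947 and 0 to 9 for duration, 2641 to 5417 and 0 to 1 for the 1-day changes, 74 to 125 and 7 to 36 for the 5-day changes, 8549 to 9436 over all and 395 to 2554 against normal control. At day 28 of the 5-day clamp leaving out obstructed replicate 34 gave the 166, replicate 33 the 980, and replicates 32 and 35 and shams 37 and 39 gave 317, 3.0e+02, 351 and 294. Normal controls 1 to 4 each moved theirs (395, 550, 505 and 2554). Obstructed replicate 5 of the 1-day clamp at day 0 moved the change to day 10 (5417), replicate 8 of day 10 the duration difference (445), and replicate 33 of the 5-day clamp that of day 28 (9). For the 5-day change from day 10 to 28 these were obstructed replicates 26, 28 and 29 of day 10 and 34 and 35 of day 28. The counts of 5 and 1 genes of the 1-day clamp at days 10 and 28 changed with most arrays.

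Signal over background limits dim genes: 20150 genes were tested without a filter and 15805 with the stricter one. On the weak arrays kidney signal over background was 4 to 7 units in the median, against 36 to 261 elsewhere.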

Other observations

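The lists in this part, and the tests of the sex-linked transcripts, were chosen only after the results were seen. The lists were written around genes already seen to change, so counts and medians are given and no p here. Acute-phase genes, usually expressed in liver, rose at release: 7 of 14 after the 1-day clamp (median 1.67, and 0.707 with 7 of 14 without the weak arrays) and 8 of 14 after the 5-day clamp (median 1.4), with 4 at its day 10. Eosinophil genes rose at days 0 and 10 of the 5-day clamp (5 of 11 at each, medians 0.319 and 0.44). Clock genes of the Dbp phase fell at day 0 of the 1-day clamp (6 of 11) and days 0, 10 and 28 of the 5-day clamp (5, 9 and 4 of 11, medians -0.56, -1.04 and -0.85). At days 0 and 10 of the 5-day clamp 7 and 4 of 14 cornified envelope genes rose and 6 and 7 of 18 cholesterol synthesis genes fell, with 4 and 7 at day 0 of the 1-day clamp.

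Sex is not given in the sources used here. Xist was high on 35 arrays and low on 40, the 4 normal controls among the low ones. A model with Xist as a term beside the groups called 6336 genes (3537 higher and 2799 lower on arrays high in Xist, 7070 in all without the weak arrays). Among them Acsm3 (-6.17), Slc7a13 (-6.02), Cyp2j13 (-5.51) and Cyp7b1 (-3.71) were lower, and Slc7a12 (4.35), Hdc (3.50), Slc22a29 (3.42) and Abcc3 (3.02) higher, while Kap (-0.40, adjusted p = 0.115) and Slc22a6 (-0.36, adjusted p = 0.0678) did not pass. These array groups are defined from the data, so the counts describe them and test nothing about mice.

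A hypothesis formed here was that obstruction acts differently on the arrays high in Xist. By limma its effect was more positive on arrays high in Xist in 43 genes and more negative in 163 (2809 at unadjusted p under 0.05). Slc7a12 (-3.29), Gc (-1.70), Clic6 (-1.68) and Fgg (-1.50) were among the more negative and Kif20b (1.64) among the more positive. With Xist as a term in the model 859 genes were called at day 28 of the 5-day clamp in place of 530, and all 530 were among them in the same direction.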
